A study of Mus musculus with 16 samples.

How the data were processed

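CUT&RUN had been done on HSCs sorted from mouse bone marrow as CD41pos or CD41neg, with antibodies to RUNX1 and to H3K4me3, in WT and RUNX1 KO mice. The labels held 16 samples in 8 groups, and 8 libraries had values in the tables used. Per the submitters' processing notes, the tools were FastQC 0.11.7, Trim Galore 0.4.2, cutadapt 1.9.1, Bowtie2 2.3.4.1, MACS2 2.1.0, bedtools 2.27.0 and featureCounts 1.6.2, with genome build mm10. For each antibody and cell type, the authors gave 1 table of annotated peaks with a raw count per library and 1 with TPM, 4 of each kind. The deposited count values were whole numbers, and whether they count reads or fragments was not given in the sources used. The deposited TPM values equalled the counts divided by peak length and rescaled to a fixed sum over all peaks, to the decimal given. How peaks were merged, whether duplicates were removed, and whether a spike-in or control library was used were not given in those sources, so a difference in signal shared by all peaks cannot be seen.

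Counts were the main values. Mitochondrial peaks were set aside for H3K4me3 ratios, RUNX1 matching and lists. H3K4me3 ratios of KO over WT used a pseudocount of 0.5 and TMM factors, for peaks with a mean count of at least 20. Each ratio has an exact 95% Clopper-Pearson interval from the share of its counts that came from the KO library. Intervals of a difference between 2 ratios, and of the ratio of overlap rates, are normal approximations on the log scale. Intervals cover counting error only, since they were computed from counts alone, with no measure of variation between libraries. They would be too narrow if duplicates had been counted. A count of 0 was replaced by a floor of 3 counts per library for a lower bound. Peaks at least 2-fold apart were counted, beside the number that Poisson noise alone gave in 100 simulations. Because each H3K4me3 group held 1 library, no test was run within a cell type. A fit with cell type and genotype as additive terms over the 4 H3K4me3 libraries (edgeR, and DESeq2 as a second tool), with 1 residual degree of freedom at 26744 matched peaks, was added after the data were seen.

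A peak of the CD41pos table was matched to one of the CD41neg table when the overlap was reciprocal at 0.5 and 1:1. Ratios between cell types were scaled for peak length, except over clusters of overlapping peaks. The RUNX1 comparison of WT CD41pos and CD41neg used 2 libraries on each side, with edgeR 4.0.16 (quasi-likelihood, two-sided, TMM, peak length as offset, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3 with limma 3.58.1, and DESeq2 1.42.0 as a second tool. Overlaps were computed with bedtools 2.31.1, beside 100 shuffles of the peaks within chromosomes. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Of 31306 symbols in the tables, 28494 (91.0%) were among the RefSeq symbols. A promoter peak is one with that class in the deposited annotation, read as within 1 kb of a transcription start site.

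The 17 gene lists (453 genes in all) were written before the data were examined: megakaryocyte and platelet, HSC, erythroid, granulocyte-monocyte, lymphoid, known RUNX1 targets, ribosomal protein, ribosome biogenesis, interferon and inflammatory, p53, cell cycle, AP-1 and immediate early, mast cell and basophil, stromal and endothelial, non-haematopoietic, housekeeping and sex-linked genes. Several lists share members, among them 23 of the 33 RUNX1 targets. Each gene was represented by its promoter peak with the highest mean count. A list's median was placed among 10000 random lists matched on mean count in 20 bins (seed 7), and called outside below the 2.5 or above the 97.5 percentile, as a description of these libraries. For the alternatives, 1000 random lists were drawn. RUNX1 peaks at lists were set against random coding genes of matched length. The symbols Cavin2 and Pldn were read as Sdpr and Bloc1s6.

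The rule for naming genes was the 10 largest ratios each way among peaks past the test with a mean count of at least 20, 1 peak per gene. It was applied without its p-value part where no test existed, with 5 each way for the difference between cell types, and list members were named by the size of their ratio. One peak that the rule names in CD41neg is not reported here. Naming promoter peaks apart, promoters alike in both cell types, removal of the trend over mean count, clusters of overlapping peaks, the filter of at least 8 counts in both libraries and the symbol aliases were chosen after the data were seen. Some RUNX1 peaks were named after their values were seen, as were Itga2b and Runx1 peaks of the cell-type comparison.

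The steps were tested on simulated data. For H3K4me3, the simulated counts held Poisson noise alone, with no variation between mice or libraries. In them, 100% of simulated 4-fold and 8-fold differences were recovered and 0.357% (CD41pos) and 0.355% (CD41neg) of unchanged peaks passed 2-fold. These shares are therefore not error rates for the real libraries. Of 100 random lists, 4 and 2 fell outside the range. For RUNX1 at 10 times the depth and a dispersion of 0.1, 95.0% of 4-fold and 100% of 8-fold differences were recovered, with 3 false calls. For the added H3K4me3 fit, 100% of 200 simulated 4-fold differences were recovered, with 6 false calls. Those 4 simulated libraries were drawn independently at a single dispersion, with no effect shared by libraries of the same mouse. The 6 false calls are therefore not an error rate for the calls in the real libraries.

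Other alternatives were size factors, total counts, upper-quartile factors, TPM with a pseudocount of 1 or 0.1, other filters, promoter or autosomal peaks alone, a reciprocal overlap of 0.8 or any overlap, each replicate left out, and a replicate block. RUNX1 in KO libraries, and with it the RUNX1 comparison of genotypes, its difference between cell types, and the cell-type comparison within KO, were not analysed here. The planned tests of H3K4me3 within a cell type and of its difference between cell types were not run, since those designs leave no residual degrees of freedom. Set tests of gene lists (camera) were not run. The RUNX1 fit used 4 WT libraries where 8 libraries had been planned.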

Results

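The transcription factor RUNX1 and the histone mark H3K4me3 were profiled by CUT&RUN in haematopoietic stem cells (HSCs) sorted from mouse bone marrow as CD41pos or CD41neg, in wild-type (WT) and RUNX1 knockout (KO) mice. CD41 is the integrin encoded by Itga2b and is carried by platelets, megakaryocytes and HSCs biased towards the megakaryocyte lineage. In CUT&RUN, an antibody directs a nuclease to its target in intact cells, and the released DNA is sequenced. H3K4me3 lies at the promoters of active and poised genes. GEO's labels described 16 samples in 8 groups of 2. Values of 8 libraries were used, namely both WT RUNX1 libraries of each cell type and replicate 2 of H3K4me3 in each genotype and cell type. The other 8 samples, among them every RUNX1 library of KO mice, were not analysed here, so RUNX1 binding was not compared between genotypes. Each H3K4me3 group held 1 library, so no H3K4me3 difference within a cell type has a replicate check or a p-value.

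The RUNX1 tables held 32957 peaks in CD41pos and 47134 in CD41neg, and for H3K4me3 there were 41083 and 39032. Counts in RUNX1 peaks summed to 569211 and 703472 in CD41pos replicates 1 and 2, and to 736891 and 710708 in CD41neg replicates 1 and 2. Outside repeat regions and mitochondrial peaks the sums were 245789, 251945, 341502 and 368489. Counts in H3K4me3 peaks summed to 7372958 (WT CD41pos), 9942889 (KO CD41pos), 8867836 (WT CD41neg) and 14306351 (KO CD41neg). A median RUNX1 peak held 5 to 8 counts per library, and a median H3K4me3 peak 43 to 83. Promoter peaks made up 41.2% and 43.5% of the H3K4me3 peaks but 6.34% and 7.32% of the RUNX1 peaks (CD41pos and CD41neg). Intervals below are exact 95% binomial (Clopper-Pearson) intervals, except those of differences between 2 ratios, which are normal approximations on the log2 scale, and all cover counting error only.

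Runx1, the targeted gene, was examined first. At its distal promoter (chromosome 16, 92822747 to 92826469), H3K4me3 held 1921 counts in the WT and 2409 in the KO library of CD41pos HSCs, a log2 ratio of -0.18 (-0.27 to -0.09). In CD41neg HSCs the distal promoter held 1785 and 3070 counts, a log2 ratio of 0.12 (0.03 to 0.20). The proximal promoter had log2 ratios of 0.00 (-0.22 to 0.23) in CD41pos and 0.17 (0.00 to 0.35) in CD41neg. This mark can persist at the promoter of a gene whose product is lost, so these values do not check the genotype labels. Itga2b, the gene of CD41, served as a check of the sort. Over its promoter region, counts were summed over the cluster of overlapping peaks with no scaling for peak length, unlike the cell-type ratios of other genes below. The WT libraries held 472 counts in CD41pos against 299 in CD41neg HSCs, a log2 ratio of 0.95, and the KO libraries 1019 against 743, a log2 ratio of 0.91.

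The first comparison asked what loss of RUNX1 does to promoter marking in CD41pos HSCs; the series title names the differentiation of megakaryocyte-primed HSCs as its subject. Megakaryocyte and platelet promoters had a small median log2 ratio of 0.07, which was high only relative to matched random lists. They were led by Treml1, a receptor of platelet granules (118 and 540 counts, log2 ratio 1.68), the platelet lipoxygenase gene Alox12 (1.16), Gp9 (0.91) and Gp5 (0.80), with Itga2b at 0.60 (0.45 to 0.76). Promoters of HSC genes were lower as a group: Robo4 had a log2 ratio of -1.44 (-1.76 to -1.13), Procr, which encodes the HSC surface receptor EPCR, -1.14 (-1.46 to -0.83), Prdm16 -0.88 and Fgd5 -0.71. Cd48, whose product marks multipotent progenitors and is absent from most HSCs, was among the 10 promoters with the largest positive ratios (226 and 1321 counts, log2 ratio 2.04, 1.84 to 2.25). Of 10 mast cell and basophil promoters, 4 were more than 1.5-fold higher in the KO library: Cpa3, a mast cell carboxypeptidase, held 21 counts in WT and 154 in KO (log2 ratio 2.34, 1.71 to 3.10), Ms4a2, a chain of the IgE receptor, 14 and 74 (1.86), Hdc, the enzyme that makes histamine, 29 and 135 (1.69), and Il1rl1, the receptor of interleukin-33, 87 and 395 (1.67). The other 6 were below 0, and the median of that list was -0.29.

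Of the 17 gene lists, 6 had a median log2 ratio outside the central 95% of 10000 random lists of the same size and mean count in CD41pos, as a description of these libraries. The megakaryocyte and platelet list lay above that range (median 0.07 over 33 genes, 8 of them more than 1.5-fold higher and 2 more than 1.5-fold lower), with Mmrn1, a platelet granule protein, at -1.15 against the direction of the list. The HSC list lay below it (median -0.27 over 34 genes, 29 of them below 0), and Slamf1, which encodes the HSC marker CD150, went the other way at 0.52. The ribosomal protein list (-0.18 over 72 genes, where matched random lists had a median of -0.10) and the sex-linked list (-0.58 over 5 genes) were also below. The sex-linked list was drawn up from Xist and Y-linked genes. With 1 library per genotype, a difference in sex cannot be told apart there from one of genotype. The cell cycle list (0.06) and the known RUNX1 targets (-0.02) were above. The cell cycle list came within the range when counts were summed over all peaks of a gene, at -0.05. The RUNX1 target list came within it with the trend of the ratio over mean count removed, at 0.07, and when counts were summed, and its median was above 0 with scaling by total counts (0.06). The mast cell and basophil list was within the range, and came below it with counts summed over peaks (-0.28 over 14 genes). The other lists within the range were the erythroid (-0.18), granulocyte-monocyte (-0.03), lymphoid (-0.13), ribosome biogenesis (-0.13), interferon and inflammatory (-0.13), p53 (-0.06), immediate early (-0.07), stromal and endothelial (-0.17), non-haematopoietic (-0.53) and housekeeping (-0.17) lists. With scaling by total counts, the granulocyte-monocyte, p53 and immediate early medians were above 0 (0.04, 0.01 and 0.00), and with counts summed over peaks the granulocyte-monocyte list was above the range (0.17) and the non-haematopoietic list below it (-0.39).

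Over all peaks of CD41pos HSCs with a mean count of at least 20 (30771), 1658 were at least 2-fold higher and 1144 at least 2-fold lower in the KO library. Counting error alone gave 67.0 and 45.0 such peaks on average in 100 simulations, which leave out variation between mice and libraries. Among 15816 promoter peaks, 246 were at least 2-fold higher and 515 at least 2-fold lower. The promoters with the largest negative ratios were those of Serpinf1, a secreted serpin (96 and 6 counts, log2 ratio -4.40), Snrpn with Snurf (113 and 8, -4.24), Efemp1, an extracellular matrix protein (78 and 6, -4.10), Acss3 (-3.87), Aass (-3.81), Pcdh20 (-3.71), Ntf3 (-3.70), Ndn (-3.56), Il1rapl1 (-3.52) and Dsc2 (-3.45). Snrpn and Ndn are imprinted genes expressed from the paternal copy. The largest positive promoter ratios, besides Cpa3, Cd48 and another Hdc peak, were those of the adaptor gene Grap (14 and 166 counts, 3.02), Cd200r4 (2.82), the complement receptor gene C5ar2 (2.73), Dpep2 (2.63), Ptprb (2.33), Phc2 (2.21) and Mx1 (2.07). Among all peaks, the largest positive ratios lay outside promoters, at Gas6 (2 and 47 counts, 3.74, 2.12 to 7.14), Ralgps2 (3.71, 2.08 to 7.11), Chst11 (3.44, 1.79 to 6.84), upstream of Cd48 (6 and 92 counts, 3.33), Unkl (3.32, 1.89 to 5.85), within Cd48 (15 and 213 counts, 3.28), Spink13 (3.13, 1.69 to 5.67), Mapre2 (3.07) and Bmp7 (3.07), and the peak in Fam13c (-3.53) was among the 10 most negative. Peaks at least 2-fold higher made up 59.2% of those apart by 2-fold, and 45.2% with the trend over mean count removed. With at least 20 counts in both libraries they made up 39.7% (480 higher and 730 lower).

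In CD41neg HSCs, erythroid promoters were higher as a group in the KO library. Their list had a median log2 ratio of 0.71 over 21 genes, above the range of random lists, with 11 genes more than 1.5-fold higher and 1 more than 1.5-fold lower. Gata1, the master regulator of erythroid and megakaryocyte genes, held 188 and 1065 counts (1.83, 1.61 to 2.07), Rhd, a red cell membrane antigen, 61 and 343 (1.81, 1.43 to 2.24), the spectrin anchor Ank1 115 and 534 (1.54), and the erythroid regulator Klf1 595 and 1893. Hba-a1, an alpha globin gene, was lower at -1.43 (-2.29 to -0.63). HSC promoters were lower as a group (median -0.20 over 34 genes, 25 below 0), with Robo4 at -1.44, Procr at -1.36, Fgd5 at -1.36 and Prdm16 at -1.01, while Slamf1 was at 0.73.

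The cell cycle list (median 0.35 over 32 genes, Cdc6 at 1.14, 0.96 to 1.33) and the ribosomal protein list (0.32 over 72 genes, 70 above 0, where matched random lists had a median of 0.19) were above the range of random lists in CD41neg, and the stromal and endothelial list (-0.82 over 12 genes, with Lepr at -2.67 and Emcn at -1.50) was below it. The stromal and endothelial list came within the range when counts were summed over all peaks of a gene. With the trend over mean count removed, the cell cycle median was 0.16, the ribosomal protein median 0.13 and the HSC median -0.32, each still outside the range. The megakaryocyte and platelet list was within the range (-0.02), since its members went both ways: Treml1 had a log2 ratio of 1.47, Itga2b 1.26, Gp5 1.08 and Gp1ba 0.98, against Mmrn1 at -2.37 (1838 and 566 counts, -2.50 to -2.23), Mylk at -1.27, P2ry12, the platelet ADP receptor, at -1.07 and Itgb3 at -0.85. A neighbouring Itga2b exon peak had a log2 ratio of 0.22 (-0.03 to 0.48). The mast cell and basophil list was within the range (-0.00 over 9 genes), with Hdc at 2.92, Il1rl1 at 1.96 (194 and 1199 counts) and Cpa3 at 1.77. Medians within the range were those of the granulocyte-monocyte (-0.25), lymphoid (-0.37), known RUNX1 target (0.09), ribosome biogenesis (0.23), interferon and inflammatory (0.03), p53 (-0.04), immediate early (0.15), non-haematopoietic (-1.07), housekeeping (0.21) and sex-linked (-0.45) lists. The granulocyte-monocyte and lymphoid lists were below the range with the trend removed, the lymphoid list also with scaling by total counts (-0.39), and the known RUNX1 targets were below it with counts summed (-0.01). The p53 and megakaryocyte medians were above 0 with upper-quartile scaling (0.01 and 0.02).

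**Figure D1:**
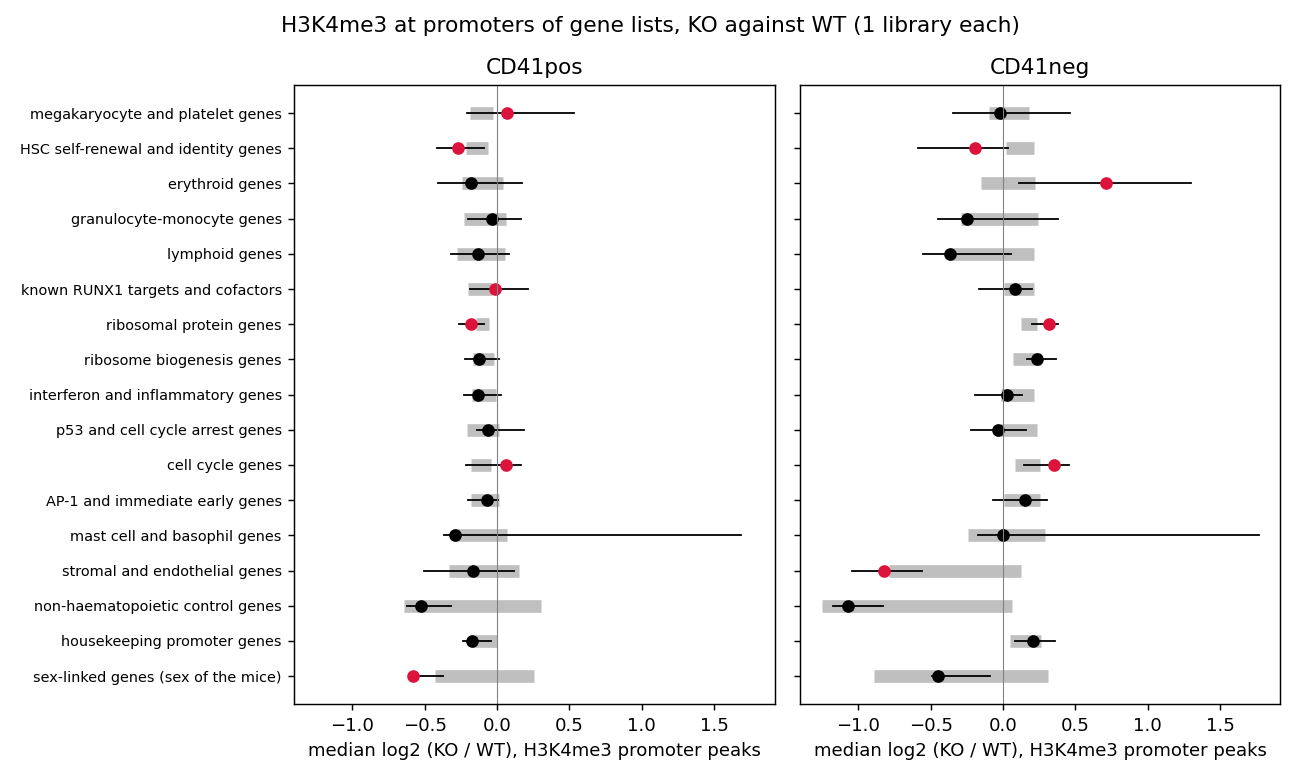
Median log2 ratio of H3K4me3 counts in KO over WT libraries (horizontal axis) for the promoter peaks of 17 gene lists, in CD41pos (left) and CD41neg HSCs (right), 1 library per group. Points are medians, red where outside the central 95% of random lists (grey bars), and black lines span the middle quartiles of the list's genes; the erythroid list lies at 0.71 in CD41neg and the HSC list below the grey bar in both.

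Over all 32104 peaks of CD41neg HSCs with a mean count of at least 20, 1851 were at least 2-fold higher and 4052 at least 2-fold lower in the KO library, against 74.0 and 43.6 from counting error alone. Counting error leaves out variation between mice and libraries, so the excess cannot be credited to genotype. Of 16229 promoter peaks, 276 were at least 2-fold higher and 1750 at least 2-fold lower. The ratio was lower at weak promoters: the median log2 ratio of tested promoters was -0.63 in the weakest bin of mean count and 0.13 in the strongest. The most negative promoters, named next, were weak peaks, so part of each ratio may go with this trend. The promoters with the most negative ratios were those of Hdac9 (76 and 1 counts, log2 ratio -6.34, -12.24 to -4.39), Pak7 (73 and 2 counts, -5.54, -8.93 to -3.95), Zfp804a (65 and 2 counts, -5.38, -8.77 to -3.78), Mnda (118 and 5, -5.10), Cdh12 (53 and 2, -5.09, -8.48 to -3.47), the glutamate receptor gene Gria4 (48 and 2, -4.94, -8.34 to -3.32), Il1rapl1 (163 and 8, -4.93), Nrg1, a neuregulin (-4.64), Col5a2 (38 and 2, -4.61, -8.01 to -2.96) and Kcnt2 (-4.55). Outside promoters, the peaks at AU022751, Rnf216 and Il1r1 were at -4.94 (-8.34 to -3.32), -4.78 (-7.31 to -3.37) and -4.68 (-8.08 to -3.04). Promoters on the higher side were led by Ssbp3 (1 and 43 counts, 4.19, 2.20 to 10.10), Iqgap2 (3.13), Hdc, Msmb (2.88), Zfp217 (26 and 297 counts, 2.82), Ly6g6d (2.72), Rab44 (39 and 395 counts, 2.66), Serpina3h (2.62), Gpr146 (2.56) and Cd200r4 (2.48). Among all peaks, those at Stk25, Fam184a, Ttpal, Mapre2 and Lats2 held 0 counts in WT, and measured against a floor of 3 counts they were higher by log2 ratios of at least 3.75, 3.42, 3.27, 3.21 and 3.11. The lower limits of their exact intervals were 3.41, 3.07, 2.92, 2.85 and 2.74. They were followed by Agbl1 (1 and 70 counts, 4.89, 2.94 to 10.79), Cmah (6 and 211 counts, 4.36) and Adcy7 (1 and 47 counts, 4.32, 2.34 to 10.22). Peaks at least 2-fold higher made up 31.4% of those apart by 2-fold, and 44.0% with the trend over mean count removed (2502 higher and 3181 lower).

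The ratios of the 2 cell types were then set side by side at 26744 H3K4me3 peaks that matched 1:1 between the tables and held a mean count of at least 20. Across peaks, which are not independent replicates, the KO over WT ratios had a Pearson r of 0.525 and a Spearman rho of 0.398. At least 2-fold higher in both cell types were 310 peaks, where independent lists would share 35.6, and at least 2-fold lower in both were 671, where independent lists would share 91.5. These expected numbers make no allowance for mean count, and weak peaks pass 2-fold more easily in both cell types. Among tested promoters, the SD of the log2 ratio was 0.957 (CD41pos) and 1.31 (CD41neg) in the weakest bin of mean count. In the strongest bin it was 0.190 and 0.257. The excess over the expected numbers therefore cannot be credited to a shared effect of genotype. A fit with genotype and cell type as terms over the 4 libraries, chosen after these results were seen, called 385 peaks as higher and 1389 as lower in KO by edgeR, and 99 and 561 by DESeq2. At an unadjusted p under 0.05 there were 4456 and 2443 peaks. Its 1 residual degree of freedom measures how the KO effect differs between cell types, not how mice differ, and replicate 2 of each cell type may come from the same mice, which the labels do not say. Promoters on the higher side in both included Cd200r4, Phc2, C5ar2, the cannabinoid receptor gene Cnr2, Hdc, Il1rl1, Slc41a3, Spink2, Rab44, Treml1, Iqgap2 and Ecm1. Those on the lower side in both included Efemp1 (log2 ratios of -4.08 in CD41pos and -3.99 in CD41neg over the matched peaks), Acss3, Snrpn, Il1rapl1, Dsc2, Pcdh20, Evc, Tmem47, Ntf3, Lin7a, Fgl1, Aass, Mdga2, Lrrc7 and Dpyd.

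**Figure D2:**
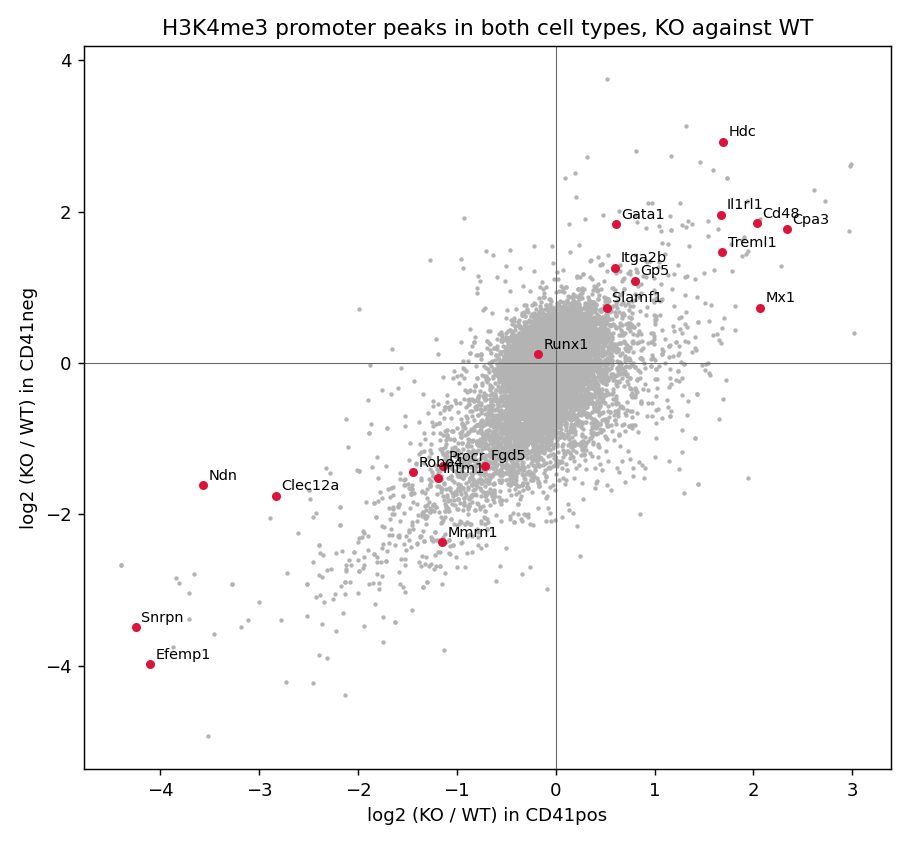
Log2 ratio of H3K4me3 counts in KO over WT at the promoter peaks of 17267 genes with a mean count of at least 20 in both tables, in CD41pos (horizontal axis) and CD41neg HSCs (vertical axis), 1 library per group. Red points are genes picked to show the range; Hdc, Il1rl1 and Treml1 lie on the higher side and Efemp1, Snrpn and Robo4 on the lower side in both.

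The difference between the 2 ratios was at least 2-fold, with the ratio higher in CD41pos, at 2611 of these peaks, and at least 2-fold with the ratio higher in CD41neg at 479. Each difference carries the counting error of 4 counts, which alone can pass 2-fold at weak peaks. How many would do so was not computed. The erythroid list had the most negative difference of any list, a median of -0.60 over 15 genes with 13 below 0. The ribosomal protein list had a difference of -0.42, with 72 of 72 genes below 0, where matched random lists had a median of -0.23. The lymphoid list had one of 0.50 over 14 genes, with 11 above 0. Also outside the range of random lists were the ribosome biogenesis (-0.37) and housekeeping (-0.39) lists, below, and the granulocyte-monocyte (0.28), megakaryocyte (0.02), HSC (0.01) and known RUNX1 target (-0.04) lists, above. Leaving out a Lats2 peak with 0 counts in WT CD41neg, largest among single peaks at genes with a name were Rgs7bp (3.52, 2.28 to 4.75), Lep (3.49), Gse1 (3.48, 1.77 to 5.18) and Plcg2 (3.43) on the CD41pos side, and Agbl1 (-3.64, -6.17 to -1.10), Jarid2 (-3.14, -5.62 to -0.66), Tnip3 (-3.04, -4.72 to -1.35) and Blm (-2.85, -4.62 to -1.09) on the CD41neg side, each with 1 to 3 counts in WT CD41neg. None of these differences has a replicate check.

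The next comparison asked how CD41pos and CD41neg HSCs differ within one genotype. In WT, CD41pos HSCs carried more H3K4me3 at megakaryocyte and platelet promoters, with a median log2 ratio of 0.33 over 31 genes, 25 of them above 0 and the list above the range of random lists. Vwf, von Willebrand factor, held 56 counts in CD41neg and 197 in CD41pos (log2 ratio 1.70, 1.28 to 2.17), Sdpr, which encodes the caveolar protein cavin-2, 165 and 601 (1.66, 1.41 to 1.92), and Plek, the platelet protein pleckstrin, 389 and 616 (1.30, 1.12 to 1.49). On the CD41neg side lay Hoxd3 (-2.10) and C5ar2 (-1.99), and, of 34 HSC genes, 11 were below 0, among them Gfi1 (-0.75), Ly6a, which encodes Sca-1 (-0.70), and Procr (-0.47), and 23 were above 0. In KO libraries the megakaryocyte and platelet list had a median of 0.46 over 32 genes, with Vwf at 64 and 427 counts (2.77, 2.40 to 3.18), Sdpr at 2.24, Mmrn1 at 1.58 and Itgb3 at 1.33. Erythroid promoters were lower in KO CD41pos than in KO CD41neg HSCs, with a median of -0.35 over 17 genes, Add2 at -2.84 (235 and 12 counts), the blood group gene Kel at -2.55, Ank1 at -2.23, Tspo2 at -2.08 and Sphk1 at -1.74.

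By this measure, 311 of 26458 matched peaks were at least 2-fold higher in CD41pos and 362 in CD41neg in WT, and 1260 and 149 of 28233 in KO libraries. Lists above the range of random lists in WT were also the HSC (0.20), erythroid (0.15), ribosomal protein (0.19), ribosome biogenesis (0.18), cell cycle (0.21), housekeeping (0.19) and sex-linked (0.29) lists, and the granulocyte-monocyte (-0.16) and p53 (-0.10) lists were below. In KO libraries the HSC (0.05), granulocyte-monocyte (0.15), lymphoid (0.14), known RUNX1 target (-0.08), interferon and inflammatory (-0.06) and stromal and endothelial (0.45) lists were also above and the ribosomal protein list (-0.29) below. The counts were scaled for peak length, which differs between the tables. Summed over clusters of overlapping peaks with no such scaling, 781 and 968 clusters were apart in WT and 2206 and 470 in KO. In that setting the WT HSC (0.11), erythroid (-0.09) and granulocyte-monocyte (-0.09) lists came within the range, while the megakaryocyte list was at 0.43 in WT and 0.64 in KO. In KO libraries the interferon list came within the range (-0.09) and the cell cycle list above it (-0.10).

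RUNX1 peaks in WT HSCs were then described by the genes they lie at. In CD41neg HSCs, 17 of 22 immediate early and AP-1 genes had a RUNX1 peak, where random coding genes of matched length had 10.7 on average (99.8 percentile of 10000 random lists). The promoter peaks among them held few counts in replicates 1 and 2: 4 and 6 at Fosl1, 6 and 16 at Fosl2, 1 and 9 at Ier2, 3 and 6 at Nr4a1, and 16 and 1 at Maff. In CD41pos the immediate early list lay at the 79.8 percentile. No allowance was made for the 17 lists placed in 2 cell types, and random genes were matched on length alone. Known RUNX1 targets had a peak at 23 of 33 genes in CD41pos (97.3 percentile) and at 25 in CD41neg (92.3 percentile), both within the central 95% of random lists. HSC genes had one at 24 and 28 of 35 (93.2 and 96.1 percentile), and megakaryocyte genes at 25 of 37 in each cell type. Promoter peaks lay at Itga2b in CD41pos (12 and 5 counts in replicates 1 and 2) and in CD41neg (6 and 9 counts), at Vwf (5 and 19) and Gfi1b (4 and 2) in CD41pos, and at Spi1, which encodes the myeloid regulator PU.1 (4 and 17), Mecom (9 and 15), Slamf1 (7 and 10) and Nfe2 (17 and 8) in CD41neg. Runx1 itself had 4 peaks in CD41pos and 12 in CD41neg. The sex-linked genes had fewer peaks than the range of random lists (0 of 6 in both cell types), and in CD41pos the non-haematopoietic genes lay at the lower limit of that range (4 of 22). Of 21896 coding genes, 50.5% had a RUNX1 peak in CD41pos and 60.8% in CD41neg.

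For the remaining lists, all within the range of random lists, genes with a RUNX1 peak in CD41pos and CD41neg numbered 12 and 17 of 25 (erythroid), 11 and 16 of 26 (granulocyte-monocyte), 16 and 16 of 27 (lymphoid), 31 and 34 of 72 (ribosomal protein), 15 and 15 of 30 (ribosome biogenesis), 18 and 21 of 36 (interferon and inflammatory), 11 and 11 of 21 (p53), 19 and 23 of 32 (cell cycle), 6 and 10 of 17 (mast cell and basophil), 8 and 14 of 17 (stromal and endothelial) and 11 and 14 of 24 (housekeeping). The immediate early list had 10 of 22 in CD41pos and the non-haematopoietic list 12 of 22 in CD41neg.

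In the RUNX1 libraries, 14 (CD41pos) and 11 (CD41neg) peaks in satellite repeat regions of chromosomes 2 and 9, chosen after the data were seen, took 47.3% to 64.0% of the counts of a library. Across peaks, counts of replicates 1 and 2 had a Spearman rho of -0.487 in CD41pos and -0.507 in CD41neg. In these tables, 2577 and 3229 peaks held at least 8 counts in both libraries, and 156 and 157 at least 20. In the libraries, 98.3% to 99.3% of peaks held fewer than 20 counts. A single interval on chromosome 2 (98666634 to 98667333 in the CD41pos table) took 29.5% to 35.6% of the counts of a library. RUNX1 peaks of CD41pos overlapped a CD41neg RUNX1 peak in 2.72% of cases, against 1.71% for shuffled peaks, whereas 80.5% of CD41pos H3K4me3 peaks overlapped a CD41neg H3K4me3 peak, against 3.79% for shuffled peaks. In the other direction, 897 of 47134 RUNX1 peaks overlapped (1.19% of shuffled peaks), and 83.8% of H3K4me3 peaks (3.98% of shuffled peaks). RUNX1 peaks overlapped an H3K4me3 peak of the same cell type in 5.19% of cases in CD41pos (2.71% shuffled) and 5.91% in CD41neg (2.61% shuffled).

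**Figure D3:**
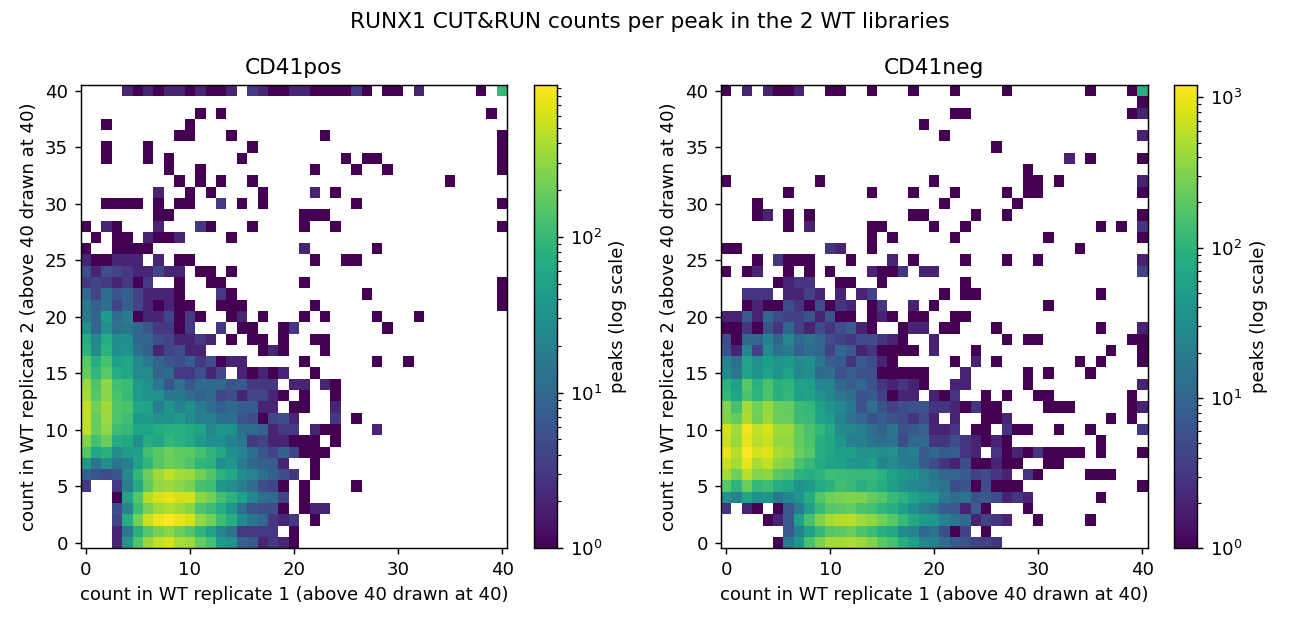
Number of RUNX1 peaks (colour, log scale) by their count in WT replicate 1 (horizontal axis) and WT replicate 2 (vertical axis), in CD41pos (left) and CD41neg HSCs (right), without mitochondrial peaks and with high counts drawn at the edge. Most peaks lie near one axis or the other, and the Spearman rho was -0.487 and -0.507.

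RUNX1 binding in WT CD41pos and CD41neg HSCs was compared at 436 peaks matched 1:1, with 2 libraries on each side. The peaks with the smallest p-values at an annotated gene were in an intron of Skint5 (6 and 24 counts in CD41pos, 5 and 62 in CD41neg, log2 ratio -1.33 ± 0.998 SE, adjusted p = 0.995 by edgeR), upstream of Sfi1 (-0.53 ± 0.464 SE), and in an intron of March1 (1.02 ± 0.951 SE), and none passed. Of 194 peaks tested by edgeR's quasi-likelihood test, 0 had an adjusted p under 0.05, 0 had an unadjusted p under 0.05, and DESeq2 called 0. Without CD41pos replicate 1, edgeR called 6 peaks as higher in CD41pos. The common dispersion was 0.563. In data simulated at this depth, with that dispersion at every peak, 44 peaks with a 4-fold and 52 with an 8-fold difference were tested. The test recovered 4.55% and 1.92% of these, so at peaks of that spread most such differences would be missed. Some peaks with high counts had smaller errors, such as one in an intron of Mdga2 (0.24 ± 0.261 SE). The simulation does not speak to those peaks.

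H3K4me3 promoter peaks that overlapped a RUNX1 peak of the same cell type were set against the other promoter peaks. In CD41pos, 882 of 15816 promoter peaks did, and their median log2 ratio of KO over WT was -0.07, against -0.09 for the others, a difference of 0.02. That median lay at the 99.8 percentile of 10000 random sets of promoters matched on count, and the difference from those sets was 0.03. In CD41neg, 1630 of 16229 did, with medians of 0.10 and 0.04 and a difference of 0.06, which was 0.01 after matching on count (88.2 percentile). These are differences of a few percent in signal, from 1 library per group.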

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

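All the tests in this part were chosen only after the results were seen.

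Over all peaks, the replicate RUNX1 libraries of a cell type rank their peaks in opposite order. At the 436 peaks matched between cell types, log2 counts of the replicates had a Pearson r of 0.718 (CD41pos) and 0.731 (CD41neg). At the 393 of these with a mean count under 60, it was -0.305 and -0.251. Counting noise near the calling limit may account for the opposite order: where the other library was higher, the lower library had a median of at most 3 counts. That value lies exactly at the limit set for the test and follows in part from sorting peaks by which library is higher. Binding that differs between the numbered mice cannot be told apart from it: peaks led by the same number overlapped between cell types at 0.853 times (0.621 to 1.17) the rate of those led by the other number, but shuffled peaks gave 115.6 overlaps on average against 157 observed. The labels also do not say that equal numbers mean the same mice.

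In the KO CD41neg library, the HSC list was lower and the erythroid list higher. A trend of the ratio with H3K4me3 count was argued against as the whole cause, since both lists lay outside random lists matched on count. With the trend removed, the medians were -0.32 and 0.59, both still outside the random lists. The removal used bins of mean count, as the matching did, so it largely repeats that control and is not separate evidence. Fewer HSCs with more of every other haematopoietic cell type cannot be told apart from a change within HSCs: the granulocyte-monocyte and lymphoid medians were -0.25 and -0.37, within the range of random lists, and, of the settings run, below it only with the trend removed or, for the lymphoid list, with total counts. A larger share of erythroid progenitors, which a sort for HSCs would be meant to remove, may also remain. Genotype was not tested within this cell type, as each group has 1 library.

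The Mx1 promoter had more H3K4me3 in the KO library in both cell types (log2 ratios of 2.07 and 0.73). An interferon response across the list was argued against: without Mx1, the interferon list had medians of -0.14 and 0.0213, and 0 of 36 genes were more than 1.5-fold higher in either cell type. More than 1.5-fold lower were 1 gene in CD41pos and 7 in CD41neg. The list also holds inflammatory genes, so a rise under 1.5-fold at the interferon genes alone could be hidden in its median. Extra copies of the Mx1 promoter, as in a transgene, could raise that peak alone, and the labels name no such transgene. The largest log2 ratio among Mx2 and other Mx1 peaks was 1.03 (0.32 to 1.86), at an upstream Mx1 peak with 20 and 66 counts, too few to decide. Genotype was not tested within either cell type.

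The ribosomal protein list differed in sign between cell types, with a median log2 ratio of KO over WT of -0.18 in CD41pos and 0.32 in CD41neg, a difference that was not tested. Random lists matched on count also differed in sign (-0.10 and 0.19), as did the housekeeping list (-0.17 and 0.21). Of the matched H3K4me3 peaks, 46 were at least 2-fold apart in opposite directions in the 2 cell types, also not tested. Mitochondrial peaks, left out of the comparisons, took 0.376% and 0.196% of the RUNX1 counts in CD41pos replicates 1 and 2, and 0.780% and 0.822% in CD41neg replicates 1 and 2. In the H3K4me3 libraries they took 0.0627% (WT CD41pos), 0.0509% (KO CD41pos), 0.0273% (WT CD41neg) and 0.0342% (KO CD41neg).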

How the results depend on the processing

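The trend, cluster and 8-count settings and the fit over both cell types below were chosen after the results were seen; the others were fixed before. Counts of peaks or lists were judged against a limit of 1.5 times, overlap shares against a binomial interval, and named peaks against the counting interval. Bound promoter differences and list medians were judged against a tolerance set by the range of random sets or lists. By these limits, 69 values of comparisons stayed within and 47 moved. Of list medians 180 stayed, 19 moved and 5, of lists outside the range of random lists, turned sign. Among those that stayed or moved, 20 medians of lists within the range turned sign. Of named peaks 934 stayed and 16 moved. Scalings shifted the median of all peaks by at most 0.07. With no count filter, CD41pos had 4749 H3K4me3 peaks higher and 3500 lower in KO, and CD41neg 3435 and 6887. With at least 20 counts in both libraries, CD41pos had 480 higher and 730 lower, and CD41neg 515 higher and 3013 lower. Promoter peaks alone gave 246 and 515 in CD41pos, and 276 and 1750 in CD41neg; fewer peaks enter by construction. With a reciprocal overlap of 0.8, also fewer peaks, the ratio was higher in CD41pos at 1475 and in CD41neg at 159, and with no filter higher in CD41neg at 906. Between cell types in WT, an overlap of 0.8 gave 117 and 133 peaks higher in CD41pos and CD41neg, no filter 762 and 716, and clusters 781 and 968. In KO, an overlap of 0.8 gave 636 and 45, clusters 2206 and 470, and no filter 246 higher in CD41neg. Overlap shares with reciprocal overlap of 0.5, the stronger peaks by count per kb, and at least 8 counts in both libraries were 1.32%, 1.89% and 6.17% for RUNX1 CD41pos in CD41neg, 0.925%, 1.31% and 5.20% for the reverse, 72.4%, 90.2% and 88.8% for H3K4me3 CD41pos in CD41neg, 76.1%, 94.3% and 89.2% for the reverse, and for RUNX1 in H3K4me3 0.847%, 3.77% and 10.5% in CD41pos and 0.719%, 5.24% and 11.3% in CD41neg. The bound promoter difference in CD41neg was 0.0121 after matching on mean count. The known RUNX1 targets in CD41pos turned to 0.0589 with total counts, 0.0221 with upper-quartile factors, 0.0249 with TPM + 1 and 0.0674 with the trend removed, and the cell cycle list to -0.0477 with counts summed over peaks. Except where fewer peaks enter, the cause was not tested. Leaving out each RUNX1 library in turn gave 0 to 6 called peaks, the 6 without CD41pos replicate 1, where the lone library is assumed to vary like the other group. With the replicate number as a block edgeR called 0 RUNX1 peaks, 0 at an unadjusted p under 0.05, and DESeq2 without it 0; deviations paired by number had a correlation of -0.00250. No paired analysis by replicate number was possible because each H3K4me3 group had 1 library; with cell type as the pair, edgeR called 385 peaks higher and 1389 lower in KO, and DESeq2 99 and 561, with 4456 and 2443 peaks at an unadjusted p under 0.05; this does not replicate the genotype within a cell type. Of the planned settings, those of KO RUNX1 libraries, tests, blocks and leave-one-out for H3K4me3 within a cell type or between cell types, and the block and estimated correlation for gene lists were not run. RUNX1 depth, 5 to 8 counts at a median peak, and a dispersion of 0.563 limit the RUNX1 comparison, and their parts were not separated.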
